A study of Mus musculus with 2 samples.

How the data were processed

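Polyadenylated RNA from the colon of adult C57BL/6J mice was measured in 2 sequencing libraries, which the labels number as biological replicates 1 and 2 of 1 group. Per the labels, the libraries were stranded, read from both ends at 76 nt on an Illumina GAIIx, and made from polyadenylated RNA longer than 200 nt after removal of ribosomal RNA, with spike-in RNAs added. The labels describe littermates of both sexes pooled and list 1 donor record for both libraries, so the spread between them may be partly technical.

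Gene, transcript, junction and contig files were used as deposited, each with its own unit. The gene and transcript tables hold expected counts, that is, read counts estimated by the authors for each feature and not normalized, 1 library per table; per the file headers these are columns of the kind RSEM writes. The same tables hold TPM (transcript abundance scaled to one fixed total over all features and spike-ins), a posterior mean of TPM, and FPKM, all as deposited by the authors. In the transcript tables the authors give the percent of a gene's abundance assigned to each transcript. Per the deposited file notes, these tables rest on the mm10 assembly with the GENCODE M4 annotation. The deposited splice junction file gives a count of reads crossing each junction, with separate counts R1 and R2 for the libraries in each junction's name, and the deposited contig file gives a signal level for each transcribed contig; both are on the mm9 assembly. Neither file ties R1 or R2 to a replicate number or says what its significance column and its tags mean. The aligner, the quantifier version, the junction and contig callers, and whether counting used the strand are not given in the sources used here. Without that last point, overlapping genes and antisense pairs such as Xist and its antisense partner are uncertain, and so are near-identical copies (haemoglobin genes, amylase genes, Try4 and Try5, the small proline-rich gene Sprr2a2, immunoglobulin segments, histones and pseudogenes), whose reads an estimated count can divide wrongly.

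Each gene table held 69691 features. Of these, 43346 were Ensembl genes, 26248 had a numeric identifier and 0 counts in both libraries, and 97 were spike-ins. Symbols, biotypes and mm10 coordinates came from GENCODE vM21 by identifier without its version, and 42462 of the Ensembl genes matched. The 884 without a symbol took 0.0964% of the counts of replicate 1 and 0.0897% of those of replicate 2. Junctions and contigs are named by mm9 position only, since no mm9 annotation was used here.

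Genes were called detected at a TPM of at least 1. The libraries were set side by side by Pearson's r and Spearman's rho of log2(TPM + 1) across genes, and by the biological coefficient of variation from edgeR 4.0.16 (R 4.3.3), the square root of its common dispersion with an intercept alone. Each gene's expected counts, rounded to whole numbers, were compared between the libraries by a two-sided exact binomial test whose expected share came from library sizes scaled by edgeR's TMM method. Above a summed count of 2000 the doubled exact tail was used. P-values were adjusted by the Benjamini-Hochberg method over genes with a summed count of at least 10, and a gene counted as differing at an adjusted p of at most 0.05 and an absolute log2 ratio of at least 1. Log2 ratios are replicate 1 over replicate 2 of scaled counts, with 0.5 added to each count. This test covers counting error only and compares 2 libraries, not conditions, so no difference has a replicate check. A fold against a count of 0 is a bound computed at 3 counts in the library at 0. Intervals are exact 95% binomial intervals, and intervals and floors cover counting error only.

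Before the data were examined, 37 gene lists, the tests and the rule for named genes were fixed. The rule takes the 20 protein-coding genes with the highest mean TPM, mitochondrially encoded genes left out, the 3 highest members of each list (6 for cells of the colon itself, and any member needed to describe a count), and the 10 genes with the largest log2 ratio in each direction among differing genes with a summed count of at least 100 and a mean TPM of at least 1. It also takes the genes of the alternative splicing list with a mean TPM of at least 5 and the 5 highest junctions and contigs. Other genes named were chosen after their values were seen, and are marked so. A list's median log2 ratio of TPM + 0.5, over members with a mean TPM of at least 0.5, was placed among 10000 random lists of the same size matched on mean TPM, and was called apart outside percentiles 2.5 to 97.5. Transcript shares are shares of a gene's TPM.

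The steps were tested on simulated data for replicate 1 against replicate 2. On counts simulated with counting error alone, the binomial test recovered 198 of 200 changed genes and called 3 unchanged genes among 17739 tested. The libraries themselves varied by more than counting error, so this rate of false calls does not carry over to them. The edgeR exact test, run as an alternative at an assumed coefficient of 0.1, recovered 200 of 200 genes changed 4-fold and called 3 others among 17713. Its counts were simulated at that same coefficient. A simulated coefficient of 0.2 was estimated as 0.201. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

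Alternatives covered other TPM minimums, FPKM and posterior mean TPM in place of TPM, TPM rescaled over nuclear-encoded protein-coding genes, other pseudocounts and count filters, median-of-ratios and total count scaling, edgeR's exact test, stricter junction and contig filters, and leaving out each library. Coordinates on mm9 and mm10 were kept apart.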

Results

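The colon, the last part of the gut, was profiled by sequencing polyadenylated RNA from adult C57BL/6J mice aged 8 weeks. There were 2 libraries of 1 group, with 46689262 expected counts in replicate 1 and 45966841 in replicate 2. With a single group, the design gives a profile of the tissue and a comparison of its 2 libraries with each other. Their counts differed by far more than sampling noise, with a mean chi-square per gene of 154. Genes with many reads and wide differences, such as Ctrb1 (310 counts against 298656), raise that mean, so it does not describe a typical gene. The libraries were kept as 2 samples, as the labels number them. Technical spread between libraries would also exceed sampling noise, so this excess alone does not show separate animals. The sex-linked reads do bear on it. Replicate 1 had 0 reads of 4 Y-linked genes against 1382 in replicate 2, and 8721 reads of Xist against 12. These values argue against 1 animal, or 1 pool of both sexes, as the source of both libraries. Levels below are TPM as mean ± SD over both libraries (n = 2) unless a library is named.

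Transcripts of the mucosal surface led the nuclear-encoded protein-coding genes of the colon. Sprr2a2, a small proline-rich protein gene with near-identical copies and therefore uncertain, was highest with 35687 ± 20003 TPM (ENSMUSG00000068893.5, chromosome 3, 92215920 to 92256724, mm10), and its level was 49831 in replicate 1 against 21542 in replicate 2. Phgr1 followed with 11989 ± 2216 TPM, then Lypd8, whose product binds flagellated bacteria at the mucosa, with 11094 ± 382 (ENSMUSG00000013643.9, chromosome 11, 58379043 to 58390728). Muc2, the gel-forming mucin of the mucus layer, reached 10226 ± 1931 (ENSMUSG00000025515.11, chromosome 7, 141690340 to 141754693). Spink4 had 7143 ± 506 TPM, the trefoil factor Tff3 5567 ± 168, the hormone precursor Guca2a (guanylin) 4727 ± 1450, and the kallikrein Klk1 4378 ± 467. The epithelial keratins Krt19 and Krt8 had 4394 ± 17.3 and 3874 ± 111. Housekeeping genes filled much of the rest of the 20 highest nuclear-encoded protein-coding genes: Rplp1 (8521 ± 1773), Actb (6354 ± 464), Cox6a1 (6295 ± 475), Rps12 (5789 ± 449), Atp5b (4938 ± 232), Cox8a (4455 ± 2042) and Fth1 (3931 ± 140). The remaining members of the 20 were Ctrb1, Cela2a and Sycn, of which Ctrb1 and Cela2a encode pancreatic digestive enzymes. Ctrb1, a chymotrypsinogen (ENSMUSG00000031957.5, chromosome 8, 111686519 to 111691010), had 12054 TPM in replicate 2 and 12.5 in replicate 1, and the elastase Cela2a had 10083 and 8.45. Sycn, a zymogen granule protein, was high in both, with 6666 and 3930. Its log2 ratio was -0.82, against -9.94 for Ctrb1 and -10.09 for Cela2a, so its level in replicate 1 did not follow theirs. The 20 genes together took 15.4% of the TPM of replicate 1 and 15.8% of that of replicate 2.

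Goblet and absorptive cell markers had the highest sums among lists of the colon's own cells. The 13 goblet cell markers summed to 36465 ± 3343 TPM and were led by Muc2, Spink4, Tff3 and Klk1, followed by Zg16 (3783 ± 497) and Fcgbp (3014 ± 137). The 14 absorptive colonocyte markers summed to 24168 ± 1456, with Lypd8, Guca2a and Krt8 ahead of the carbonic anhydrase Car1 (2447 ± 259), the water channel Aqp8 (503 ± 11.8) and Car4 (447 ± 33.0). Goblet markers thus summed to 1.47 times the colonocyte markers in replicate 1 and 1.54 times in replicate 2, and the ratios of the list medians were 2.92 and 3.74. Enteroendocrine markers summed to 2358 ± 172 TPM, most of it the peptide hormone gene Pyy (1958 ± 139), ahead of Insl5 (114 ± 23.98) and Sst (96.9 ± 9.55). Crypt stem cell markers summed to 361 ± 26.1, led by Ephb2 (113.6 ± 9.36), Lrig1 (78.6 ± 4.62) and Sox9 (56.4 ± 4.00), and proliferation genes to 196 ± 3.89, led by Pcna (60.2 ± 7.56). Tuft cell markers came to 50.9 ± 7.15, with Alox5ap at 15.8 ± 0.806 and Trpm5, a cation channel of these cells, at 7.52 ± 0.997.

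Among lists of the colon's own cells, which hold no immunoglobulin genes, smooth muscle had the next highest sum. Colonocyte markers summed to 3.16 times the smooth muscle markers in replicate 1 and 3.47 times in replicate 2, but by list medians the ratios were 1.87 and 1.67. Its 12 markers summed to 7292 ± 41.8 TPM, with Acta2 at 1903 ± 67.3, Tagln at 1633 ± 31.5, Actg2 at 1529 ± 30.8 and Cnn1 at 890.1 ± 5.88. Enteric neuron markers summed to 109 ± 3.13, led by Uchl1 (34.3 ± 5.42) and Tubb3 (22.3 ± 0.594), glial markers to 107 ± 11.02, led by Erbb3 (82.4 ± 8.71), which epithelium also expresses, and markers of the pacemaker interstitial cells of Cajal to 194 ± 13.8, led by Ano1 (157 ± 17.4) and Kit (33.2 ± 3.56). Fibroblast markers summed to 683 ± 50.2 TPM, with Col6a1 at 159 ± 12.0 and Col3a1 at 133 ± 22.6. Endothelial markers came to 200.4 ± 3.83, led by Egfl7 (101.4 ± 0.403), and mesothelial markers to 21.3 ± 6.68, led by Upk3b (11.9 ± 4.22).

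Among immune lists, macrophage markers summed to 475 ± 24.2 TPM, led by the complement gene C1qc (135 ± 25.0) and the lysozyme gene Lyz2 (115 ± 6.33). B and plasma cell markers summed to 363 ± 20.8, of which Jchain, the joining chain of secreted IgA and IgM, gave 286 ± 21.3. The list holds none of the immunoglobulin genes themselves, so its sum understates these transcripts. Igkc (5548 ± 612) and Igha (5547 ± 130), picked out after their values were seen, each far exceeded it. Annotated as immunoglobulin constant regions, both also fall outside the ranking of protein-coding genes above. T cell markers came to 15.3 ± 1.46 and mast cell markers to 3.21 ± 0.396, led by Lck (5.48 ± 1.17) and Tpsb2 (1.54 ± 0.127). The 6 MHC class II genes summed to 1670 ± 5.57 TPM, led by Cd74 (736 ± 85.3). Mucosal defence genes summed to 1313 ± 236, with the immunoglobulin receptor Pigr at 789 ± 62.6 and the antimicrobial lectin Reg3b at 383 ± 259. Interferon-stimulated genes summed to 286 ± 48.2, mostly Irf7 (222 ± 54.7).

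Functional lists gave 1269 ± 45.6 TPM for butyrate, bile acid and ion transport (the monocarboxylate transporter Slc16a1 had 112 ± 16.3), 609 ± 47.7 for immediate early and heat shock genes, led by Junb (213 ± 10.8), and 259 ± 4.04 for the circadian clock, led by Nr1d1 (111 ± 18.0). Hox genes summed to 798 ± 17.3 TPM, of which Hoxb13, expressed at the posterior end of the body axis, made 323 ± 31.2. The 16 alternative splicing genes summed to 3761 ± 125, led by Pkm (1203 ± 145). Cytosolic ribosomal protein genes summed to 55845 ± 4310 TPM, mitochondrially encoded genes to 18764 ± 5311, led by mt-Co1 (7939 ± 2098), and small nuclear and cytoplasmic RNAs to 33513 ± 3389, led by Rn7sk (15586 ± 6034). Replication-dependent histones summed to 3688 ± 382, led by Hist1h2bc (839 ± 224). Histone messages and several of these small RNAs lack a long poly(A) tail, so their levels also depend on the selection of RNA.

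Markers of neighbouring tissues were mostly low. Skeletal muscle markers summed to 88.6 ± 34.6 TPM, mainly Ckm (66.8 ± 18.6), small intestine markers to 45.7 ± 5.35, mainly Alpi (32.1 ± 6.10), liver markers to 35.5 ± 3.30, mainly Ttr (31.4 ± 3.53), and stratified squamous markers to 2.20 ± 0.849, or to 11.1 with posterior mean TPM. Haemoglobin and its partner gene Alas2 summed to 525 TPM in replicate 1 and 2998 in replicate 2, adipocyte markers to 219.9 and 474, and sex-linked genes to 15.4 and 12.1. The pancreatic acinar list is decided by 1 library: its 11 members summed to 33.1 TPM in replicate 1 and 36869 in replicate 2.

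**Figure D1:**
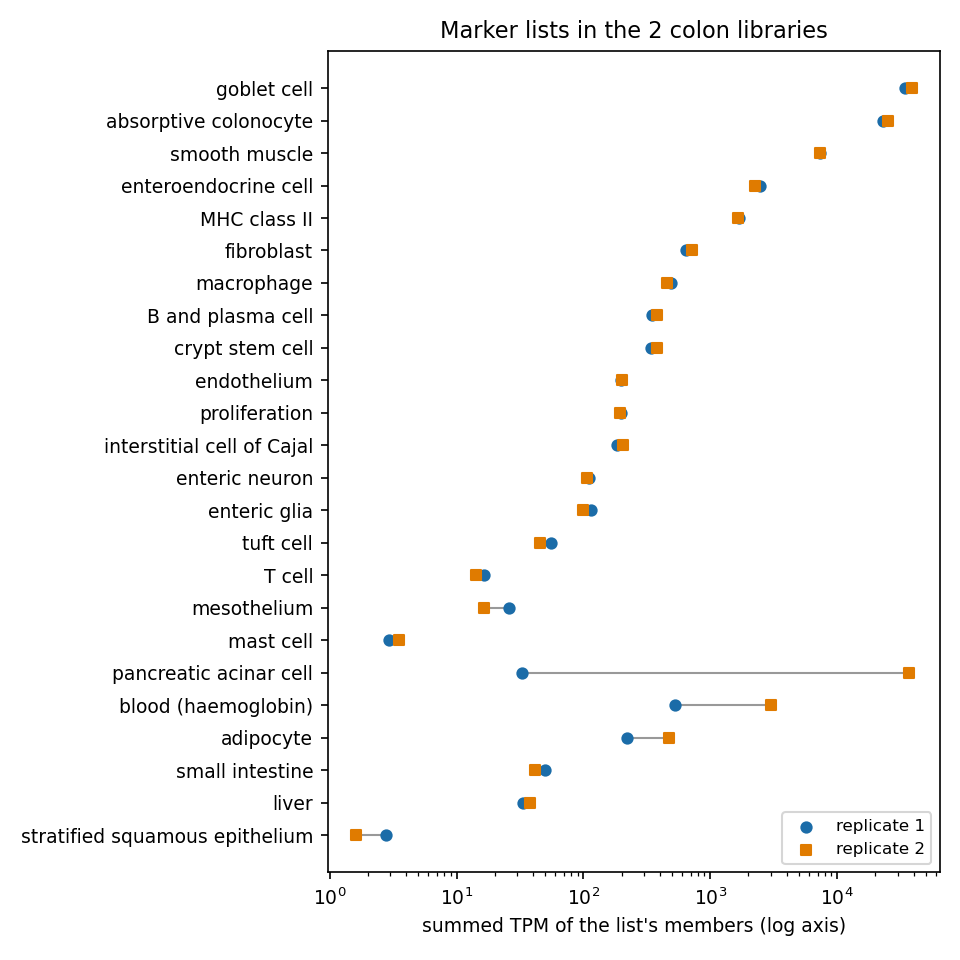
Summed TPM (log axis) of the marker lists of cell types and neighbouring tissues in replicate 1 (circles) and replicate 2 (squares), with a line joining the libraries of each list. The acinar list lies at 33.1 TPM in replicate 1 and 36869 in replicate 2, while the smooth muscle list lies at 7321 and 7262.

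A TPM of at least 1 was reached by 13638 genes in replicate 1 and 13837 in replicate 2. Both libraries shared 13287 of these, 12429 of them protein-coding, while 351 genes passed only in replicate 1 and 550 only in replicate 2. Protein-coding genes took 96.2% of the counts of replicate 1 and 95.1% of those of replicate 2, and mitochondrially encoded genes 1.52% and 1.08%. Gm42418, which overlaps ribosomal RNA sequence and was picked out after its values were seen, took 0.491% and 1.57%.

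Most genes were within 2-fold between the libraries, although 8750 of the 17713 tested (49.4%) had an adjusted p under 0.05 by the exact binomial test at any fold. The shares below cover every gene tested, the acinar genes included. Of 1533 genes with a mean TPM of at least 100, 96.9% were within 2-fold, as were 97.7% of 6197 genes between 10 and 100 and 94.5% of 6039 genes between 1 and 10. Acta2 (log2 ratio 0.05), Tagln (0.02), Tff3 (0.00) and C1qa (0.00) were among the closest list members, and Sprr2a2 (1.17) among the most distant of the highest genes. Across the 14188 genes with a TPM of at least 1 in either library, Pearson's r was 0.960 and Spearman's rho 0.963; genes are not independent replicates, and no p-value is attached. The biological coefficient of variation was 0.272 over 17713 genes.

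**Figure D2:**
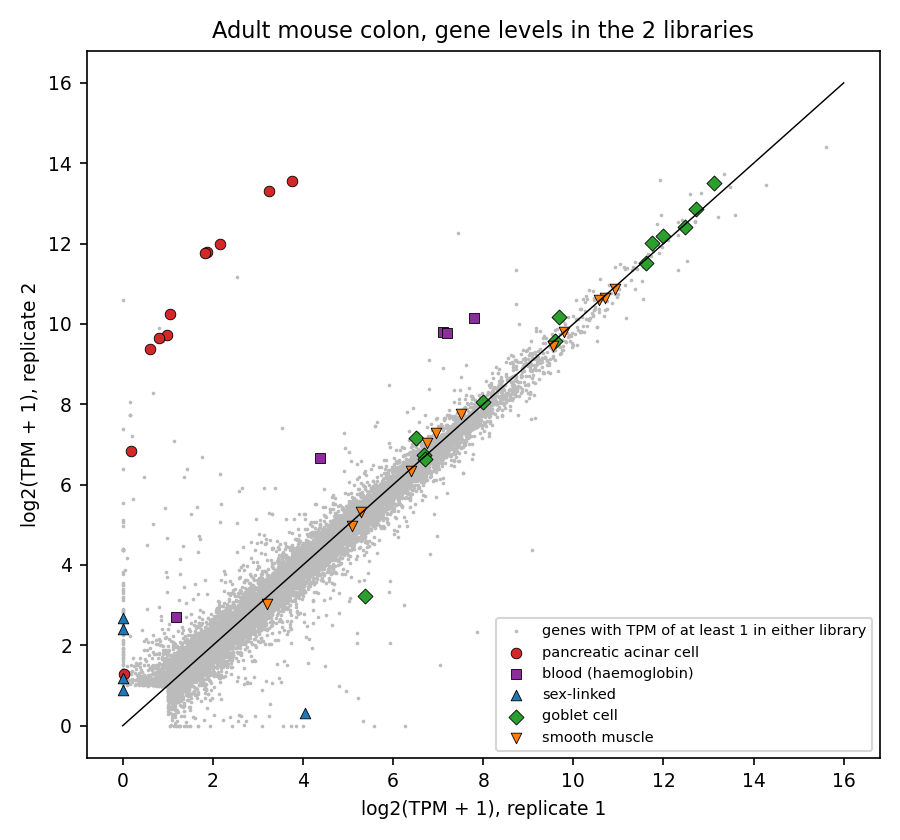
Each point is a gene with a TPM of at least 1 in either library, plotted as log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), with members of 5 lists marked and the line of equal levels drawn. Goblet and smooth muscle genes lie near the line apart from Ang4 (40.5 TPM against 8.44), while the acinar genes Ctrb1 and Cela2a lie far above it.

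Set against each other, the libraries differed widely in pancreatic and sex-linked transcripts, and in some immunoglobulin segments, pseudogenes and noncoding RNAs. In replicate 2, digestive enzyme genes made up most of the 10 largest differences: Pla2g1b, a secreted phospholipase (ENSMUSG00000029522.8, chromosome 5, 115466262 to 115474722), had 2044 counts against 0, at least 697-fold higher. Ctrc, a chymotrypsin, had a log2 ratio of -10.95, and its annotated span overlaps that of Cela2a, so the division of their reads is uncertain. The amylase copies Amy2a2 to Amy2a5 had ratios from -11.16 (Amy2a4) to -10.84, with reads that near-identical copies share. Try10 was at least 272-fold higher in replicate 2 and Pdia2, a protein disulfide isomerase of the pancreas, at least 301-fold. The other 2 were Kdm5d, a Y-linked histone demethylase (ENSMUSG00000056673.10, chromosome Y, 897788 to 956786, 886 counts against 0, at least 302-fold), and St6galnac1, a sialyltransferase (819.6 against 0, at least 279-fold). The estimated counts of Try10, Pdia2 and St6galnac1 were not whole numbers. Part of their reads was thus divided with other features, and these values are uncertain too.

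In the other direction, Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), had 8721 counts in replicate 1 and 12 in replicate 2, a log2 ratio of 9.41. Immunoglobulin segments were among the 10 largest differences, Igkv4-78 (407 counts against 0, at least 132.6-fold) and Ighv3-3 (670 against 9, log2 ratio 6.11). The rest were Gm28037 (at least 224.5-fold), ENSMUSG00000103565.1, which has no symbol (1022 counts against 0, at least 333-fold), the processed pseudogenes Gm14165 (8.71), Rplp0-ps1 (at least 65.2-fold), Gm4294 (at least 59.1-fold) and Gm9625 (5.81), and the long noncoding RNA Gm28382 (293 counts against 1, log2 ratio 7.58). Segments and pseudogenes share sequence with other genes, so these values are uncertain. The estimated counts of Gm28037 (689.03) and ENSMUSG00000103565.1 (1021.89) were not whole numbers. Part of their reads was thus divided with other features, and their values are uncertain too.

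In all, 1124 of 17713 genes tested differed by the exact binomial test, 450 higher in replicate 1 and 674 higher in replicate 2. Protein-coding genes made 279 and 430 of these out of 15549 tested, immunoglobulin segments 36 and 49 of 153, and pseudogenes 42 and 99 of 561. The test sees counting error alone: edgeR's exact test at the coefficient of variation estimated from the same libraries, chosen after seeing the data, called 236 genes, 74 higher in replicate 1 and 162 higher in replicate 2, and a minimum summed count of 100 left 414. The estimated coefficient is 1 value for all genes and takes in the differences under test. A call kept there, here and below, marks a larger fold or count and is no check against replicate spread.

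Among the fixed lists, the acinar, sex-linked and haemoglobin lists had the largest median ratios. All 11 acinar genes were higher in replicate 2, including Ctrb1 (log2 ratio -9.94), Cela2a (-10.09) and the trypsinogen Prss2 (-10.23), and the list's median of -9.61 lay at percentile 0 of random lists. All 5 haemoglobin list genes were higher in replicate 2, with Hba-a2 at -2.41 and Hbb-bs at -2.54 (median -2.36, percentile 0). In the adipocyte list 2 of 6 members passed, the adipokine gene Cfd (-1.22) and Fabp4 (-1.12), both higher in replicate 2 (median -0.61, percentile 0.03), and both lost the call in edgeR's test at the estimated coefficient of variation, chosen after seeing the data, which all acinar, haemoglobin and sex-linked calls kept. Sex-linked members split, with Xist higher in replicate 1 and Kdm5d, Eif2s3y, Uty and Ddx3y higher in replicate 2, where they had 1382 reads against 0 in replicate 1. This allows a share of at most 0.267% of their reads in replicate 1, and Xist had 0.137% of its reads in replicate 2 (95% interval 0.0710 to 0.240). The list's median of -2.55, at percentile 0, joins opposite signs.

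Smaller shifts were seen in lists of the colon's own cells. Enteroendocrine genes had a median of 0.49 (percentile 99.98), with Chgb (1.04) and Nts (1.04) higher in replicate 1 and Chga at 0.54, while Insl5 was at -0.48. Mucosal defence genes had a median of 0.48 (percentile 99.96): Reg3b (1.46), the oxidase maturation factor Duoxa2 (1.15) and the lectin Itln1 (2.32) were higher in replicate 1, and Reg3g was at -0.62. With all members of that list, those under the minimum included, its median was 0.09, inside the random range. Mesothelial genes had a median of 0.52 (percentile 99.5) with 0 of 4 past the threshold for single genes. Mitochondrially encoded genes had a median of 0.27 (percentile 98.0), which fell inside the random range, at percentile 97.2, with TMM-scaled CPM. Cytosolic ribosomal protein genes lay lower in replicate 1, with a median of -0.33 (percentile 0) and 6 of 77 past the threshold, among them Rps27 (-2.72) and Rpl39 (-1.52), all higher in replicate 2. Estimated counts can divide reads wrongly between such genes and pseudogenes, so these single values are uncertain. Fibroblast genes (-0.18, percentile 1.4) and alternative splicing genes (-0.13, percentile 0.76) also lay lower in replicate 1, with 0 members past the threshold in either. In edgeR's test at the estimated coefficient Chgb, Nts, Reg3b, Duoxa2 and 5 of the 6 ribosomal protein genes, Rpl39 among them, lost the call, and Itln1 and Rps27 kept it.

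These 11 lists of 36 tested stood apart. By their medians, 7 of them were lower and 4 higher in replicate 1, the sex-linked list with its opposite signs among the lower. Lists of genes drawn independently would give 1.8. Members of a list can move together within a library, so that number may be too low for 2 libraries. The stratified squamous list, with 1 member at a sufficient level, was not placed among random lists, though Krt5 (2.39) and Krt13 (1.75) were higher in replicate 1 at low counts and lost the call in edgeR's test at the estimated coefficient. Adjusted over the list alone, the count of differing members was the same as over all genes tested in each of the 37 lists.

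The other 25 lists lay inside the random range. Median log2 ratios were -0.09 for absorptive colonocyte, -0.06 for goblet cell, -0.14 for crypt stem cell, -0.12 for proliferation, 0.19 for tuft cell, 0.01 for smooth muscle, 0.03 for enteric neuron, 0.15 for enteric glia, 0.05 for interstitial cell of Cajal and -0.18 for endothelium. Immune lists had -0.14 (B and plasma cell), 0.11 (T cell), 0.03 (macrophage), 0.13 (mast cell), -0.11 (interferon-stimulated) and 0.11 (MHC class II). The medians were 0.07 for skeletal muscle, -0.11 for small intestine, -0.23 for liver, 0.16 for immediate early and heat shock, 0.18 for the clock, 0.13 for transport, 0.13 for small RNAs, 0.07 for Hox genes and 0.07 for histones. The mean had the other sign from the median in the colonocyte (0.08), goblet (0.01), smooth muscle (-0.03), neuron (-0.09) and mast cell (-0.16) lists. The crypt stem cell list passed to the outside, at percentile 1.97, with TMM-scaled CPM. Single members past the threshold in these lists included the bile acid transporter subunit Slc51a (2.40), the goblet ribonuclease Ang4 (2.21), the bile acid importer Slc10a2 (1.59), Fosb (1.49) and Acta1 (1.98), all higher in replicate 1. Mcpt1 (-2.15), Ms4a1 (-1.39), Usp18 (-1.14) and Lyz1 (-1.14) were higher in replicate 2. Of 34 Hox genes tested, 7 were higher in replicate 1: Hoxb4 (1.36), Hoxb7 (1.28), Hoxb6 (1.20), Hoxb8 (1.03), Hoxd4 (1.01), Hoxc5 and Hoxc10. The 1 higher in replicate 2 was Hoxd12 (-1.98). Of the genes named in this paragraph as past the threshold, Slc51a and Ang4 alone kept the call in edgeR's test at the estimated coefficient, and all 8 Hox calls were lost.

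**Figure D3:**
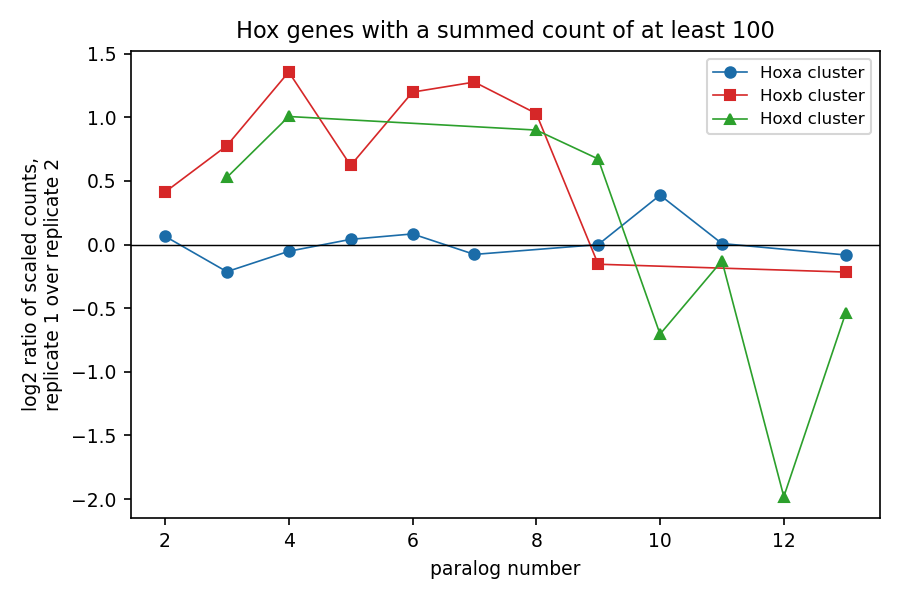
Log2 ratio of scaled counts, replicate 1 over replicate 2 (y axis), against paralog number (x axis) for the 27 Hox genes with a summed count of at least 100. There is 1 line per cluster, and no gene of the c cluster reached that count. The Hoxb and Hoxd genes lie above 0 at low numbers and at or below it from number 10 on, with Hoxd12 at -1.98, whereas the Hoxa genes lie near 0 apart from Hoxa10 (0.39).

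Transcript choice was compared in 16 genes with tissue-dependent splicing. Pkm, pyruvate kinase, was represented mainly by Pkm-201, with 89.7% ± 1.36 of its TPM (n = 2), and the myosin light chain kinase gene by Mylk-201, with 98.4% ± 0.107. Ctnnd1-202 made 68.4% ± 4.42 of the catenin gene Ctnnd1, Actn1-201 55.2% ± 0.646 of Actn1, and Cd44-203 49.7% ± 3.03 of Cd44. Myh11, Vcl and Myl6 have 1 annotated transcript in the tables, so they carry no information on choice. Of the other 13 genes, the same transcript led in both libraries for 9 and took over 50% in both for 4. Leadership changed for Tpm1, where Tpm1-215 had 27.6% in replicate 1 and 50.8% in replicate 2, for Tpm2, where Tpm2-201 had 54.5% and 44.7%, and for Smtn and Enah. Cald1-203 led Cald1 with 44.0% in replicate 1 and 54.9% in replicate 2. No transcript reached 50% in either library for Macf1 (Macf1-214, 45.1% ± 4.30), Fgfr2 (Fgfr2-211, 34.8% ± 1.37) and Ptbp1, whose leading transcript Ptbp1-207, 30.1% ± 3.78, is annotated as a target of nonsense-mediated decay. Estimates for short or overlapping transcripts rest on few distinguishing reads.

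Reads crossing splice junctions were listed for both libraries together at 402639 junctions on mm9. The most used lay on chromosome 11 on the plus strand, from 58195890 to 58196253 with 264456 reads, from 58192601 to 58195786 with 254623 and from 58196368 to 58198111 with 179565. Next came chromosome 7, 148940090 to 148940219 on the plus strand, with 179535 reads, and chromosome 5, 143667156 to 143667242 on the minus strand, with 94389. Junctions found in both libraries numbered 165052 (41.0%) and held 98.7% of the reads, and 152737 (37.9%) had 1 read. The junctions tagged A=1 in the file, a tag whose meaning is not given in the sources used here, numbered 154088 and held 91.0% of reads, and 83.0% of them were in both libraries. Those tagged A=0 numbered 248551, with 8.96% of reads and 15.0% in both. Of the A=0 junctions, 7.39% (18364) lay between 137000001 and 138000000 on chromosome 5. On chromosome Y there were 7 reads in R1 and 635 in R2. Across junctions in both, Pearson's r of log2(reads + 1) was 0.933.

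Transcribed contigs numbered 562412 on mm9, 285514 on the plus and 276898 on the minus strand, and covered 183.6 Mb. Their median length was 216 bases and the longest had 16962. The highest signal levels, as the authors give them, were 25700 at chromosome 16, 11143991 to 11144421, 10700 at chromosome 9, 110183730 to 110183889, and 6660 at chromosome X, 84483689 to 84483771, all on the plus strand. A pair of contigs on the minus strand of chromosome 5 followed, at 137632670 to 137634058 (5670) and 137625299 to 137627507 (5130). The 1000 contigs with the most bases held 39.9% of all aligned bases in contigs. A significance value of at most 0.1 was given to 282956 contigs (50.3%).

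Spike-in RNAs took 0.895% of the counts of replicate 1 (418095) and 1.02% of those of replicate 2 (467280). Of 97 spike-ins, 66 had a read in either library and 62 in both. Their log2(TPM + 1) had a Pearson's r of 0.993 and a Spearman's rho of 0.980 across spike-ins. Over the 36 with a summed count of at least 100, the median log2 ratio of counts per total was -0.19 with an SD of 0.29.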

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

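The edgeR test at the coefficient of variation estimated from these libraries, the agreement over protein-coding genes with a summed count of at least 10, and the count of differing genes without immunoglobulin segments, pseudogenes and genes without a symbol were chosen after seeing the data. Single genes were compared again only with another test or with another scaling, which moved their ratios little. Those past the threshold could therefore not change sign, and this is no check on them. Under the alternatives run, 0 genes past the threshold and 0 lists apart changed sign. Medians of 8 lists inside the random range did: with all members T cell (to -0.0086), liver (0.04), mast cell (-0.06) and skeletal muscle (-0.10, and -0.07 with a pseudocount of 0.1), and with TMM-scaled CPM smooth muscle (-0.03), enteric neuron (-0.0014), interstitial cell of Cajal (-0.0020) and small RNAs (-0.01). So did the ratios of 9 genes, of at most 0.01 in size. Detected genes ranged from 12797 to 17052 and protein-coding ones from 12022 to 14998; without replicate 1 or 2 in turn they were 13837 and 13638, and 12801 and 12639. Pearson's r was 0.987 without a filter, 0.909 over genes with a TPM of at least 10, 0.938 with a pseudocount of 0.1 and 0.979 over protein-coding genes with a summed count of at least 10; Spearman's rho was 0.938 at a TPM of at least 10 and 0.981 over those protein-coding genes. The coefficient of variation was 0.251 at a summed count of at least 100. The cause of these shifts was not tested.

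Differing genes numbered 414 at a summed count of at least 100, where fewer genes were tested, 760 with edgeR's exact test at an assumed coefficient of 0.1 and 236 at the estimated one, which lets each gene vary more. They numbered 1125 with either other scaling, 1236 without a filter and 870 without segments, pseudogenes and genes without a symbol. Of 482 named and list genes tested, 80 passed the threshold, and 6 and 37 of them lost it at the assumed and the estimated coefficient; the other scalings changed 0. Lists apart numbered 10 or 11.

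Rescaled over nuclear-encoded protein-coding genes, the colonocyte, goblet and smooth muscle lists summed to 27749, 41865 and 8373, and in FPKM to 18942, 28580 and 5715, through the change of unit itself; with posterior mean TPM smooth muscle had 7222. The stratified squamous sum, 2.20, was 11.1 with posterior means, for a cause not tested, and the sex-linked sum, 13.7, was 6.77 after rescaling, which leaves out the noncoding Xist. Leaving out a replicate gave sums from 23139 to 25198, 34102 to 38829 and 7262 to 7321. The acinar sum rests on replicate 2: it was 33.1 without it and 36869 without replicate 1. The dominant transcript count, 12 with the 3 genes of 1 transcript included, was 12 with posterior means and 13 to 15 against 1 replicate. Junctions numbered 249902 at 2 reads or more, 120859 at 10 or more and 165052 in both libraries; contigs numbered 294310 at 200 bases or more and 282956 at a significance of at most 0.1, as stricter filters remove some. The spike-in r was 0.987 with a pseudocount of 0.1. Agreement, differing genes and lists apart give no value with 1 library left. Depth limits genes near the minimum, where a count of 0 allows up to 3 counts.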

Other observations

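The comparison of immunoglobulin segments, the tests of a fixed share, of pooled sexes and of the Hox genes, and the look at Ins1 and Ins2 were chosen only after the results were seen, while the second acinar, islet and X inactivation escape lists were written before their values were seen. Immunoglobulin transcripts, which the B and plasma cell list leaves out, were abundant in the colon. Igha, the constant region of IgA, had 5455 TPM in replicate 1 and 5639 in replicate 2, and the light chain gene Igkc 5115 and 5981. Ighg1, a constant region of IgG, had 145 and 54.7, and Ighm 39.8 and 77.9. The variable segments differed more between the libraries than other genes did. Over 89 segments with a summed count of at least 100, the median absolute log2 ratio was 1.27, against 0.28 (0.21 to 0.35) for random genes of like level (percentile 100), and 57.3% of them passed the threshold, 18 higher in replicate 1 and 33 higher in replicate 2. Their summed TPM was 3568 and 4312. Ighv5-9-1 had 2 counts in replicate 1 and 435 in replicate 2, and Igkv4-58 had 108 and 2. Segments share sequence, so single values are uncertain.

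The acinar enzyme genes Ctrb1 and Cela2a were abundant in replicate 2 and low in replicate 1, and the insulin genes Ins1 (390 reads against 0) and Ins2 (771 against 0) went with them. If pancreatic tissue had been carried into replicate 2, a second acinar list and an islet list should both have had a median log2 ratio below -3; the acinar list had -3.72 (-2.40 with members at 0 set to 3 counts; Cela1 -2.65, Spink1 -0.10) and the islet list 0.60, so the test failed by the bound set for it. For the islet list that bound was ill chosen, for reasons found only afterwards: 3 of the 4 islet genes measured had a TPM of at least 1 in replicate 1, led by the hormone gene Ppy with 251 against 142 in replicate 2, where a small added share would not show, although Iapp (1.61 and 1.17) and Mafa (2.14 and 1.20) would hide less. Of the other members, G6pc2 had 9 reads in replicate 1 and 10 in replicate 2. Slc30a8 (0 and 4 reads) and Ucn3 (0 and 3) fell under the minimum summed count and were not used. A fixed share of replicate 2 material in replicate 1 was not excluded as the source of acinar reads there: the variance over counting variance was 13637 over the 13 genes of both lists with 1000 reads in replicate 2, but Spink1 and Cela1, with 48.9% and 14.0% of their reads in replicate 1, have a level of their own there, which fixes that outcome, and without them it was 48.9, or 1.97 without Pnliprp2 (2.12%) too, over the 10 such genes of the first list, close to the limit of counting error of 1.88. Tissue taken along with the colon and pancreatic RNA or reads that entered later cannot be told apart, because 1 library holds the high levels, and no biological explanation was tested.

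Sex-linked transcripts divided the libraries, with Xist in replicate 1 and Kdm5d, Eif2s3y, Uty and Ddx3y in replicate 2. Both sexes pooled in each library, as the labels have it, would put Y-linked reads in both, and replicate 1 had at most 0.267% of them. Genes known to escape X inactivation, as replicate 1 from females and replicate 2 from males would predict, had a median log2 ratio of 0.48, with Kdm5c at 0.61, Kdm6a at 0.50 and Eif2s3x at 0.45. All 4 were above 0, though Ddx3x only by 0.08, and its TPM went the other way (14.6 against 18.4). The values go with 1 sex per library. They argue against 1 animal, or 1 pool of both sexes, as the source of both libraries. Whether the label or the assignment of samples is at fault is open. Sex, animal and library are confounded in every difference between the libraries.

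Hox genes of low paralog number, expressed further forward along the body, were relatively higher in replicate 1. This was seen in the genes with a summed count of at least 100, none of them from the c cluster. Below that count, Hoxc10 passed the threshold higher in replicate 1, against the trend, and Hoxc5 went with the trend. The trend prompted the test that follows on the same genes, so its p-value is no independent support. Over 27 genes, Spearman's rho of log2 ratio with paralog number was -0.50 (permutation p = 0.00798, adjusted over 4 relations 0.0319), with a median of 0.57 for numbers up to 8 (13 of 16 higher in replicate 1) and -0.13 from 9 on (8 of 11 higher in replicate 2); these medians were 1.03 (7 of 7) and -0.19 (2 of 2) in the b cluster, 0.90 (3 of 3) and -0.54 (4 of 5) in the d cluster, and -0.0064 and 0.0035 in the a cluster. A larger mesenchymal share in replicate 1 would raise smooth muscle and fibroblast genes too, but their joint median was -0.091. The medians of these 2 lists were already known when that bound was set, so its outcome was not open. Different lengths of colon in the libraries may account for the trend, but it should then show in both the b and the d cluster, and rho was -0.74 in the d cluster (exact permutation p = 0.0458, adjusted 0.0917), -0.32 in the b cluster (exact permutation p = 0.410, adjusted 0.547) and -0.0061 in the a cluster (permutation p = 1, adjusted 1). Neighbouring genes of a cluster are not independent, and segment and animal cannot be told apart with 1 library each.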
